A study of Homo sapiens with 6 samples.

How the data were processed

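Bulk RNA-seq was carried out on THP-1-derived macrophages, with 3 libraries from cells given scrambled siRNA and 3 from cells given siRNA against TREM2. THP-1 is an established human monocytic leukaemia line. Per the labels' protocols, the monocytes were turned into macrophages with the phorbol ester PMA at 20 ng/mL, 3 days ahead of treatment. They were then transfected at 100 nM siRNA, exposed to a mixture called HT (25 mM D-glucose and 5 ng/mL TNF-α), and collected after 3 days. Libraries were strand-specific and made from polyadenylated RNA with the KAPA mRNA stranded Hyper kit, per the labels' protocols.

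The deposited values are raw counts per Ensembl gene, in 1 column per library, without normalization. Per the submitters' processing notes, the authors used Trimmomatic 0.39, STAR 2.7.10a and featureCounts with the genome build hg38. The featureCounts version and strand setting, and the gene annotation release, are not given in the sources used here. For that reason counts of genes with an antisense partner, and of genes with near-identical copies such as HLA, ribosomal protein, FCGR1A and CCL3 genes, are uncertain to the extent that reads could be shared or lost. The columns for the scrambled libraries carry the name Ctrl in the deposited table, and each column was assigned to the library with the same group and replicate number. The table holds 78933 lines. 3 of them are the pieces of 1 gene, ENSG00000155657, broken by its exon coordinates, and hold no counts. They were left out, which leaves 78930 genes, of which 44704 had a count in any library. Every line kept names a gene.

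Gene symbols came from the reference tables of gene names, which covered 61479 of the 78930 genes. Positions came from GENCODE release 29, which has the same genome build (GRCh38, hg38) but is not known to be the release used for counting. It covered 57354 genes, and genes outside it are given without a position.

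Total counts were 7394513, 30149984 and 23721037 in scrambled replicates 1, 2 and 3, and 12964122, 6689159 and 21513367 in knockdown replicates 1, 2 and 3. The deepest library held 4.51 times the counts of the shallowest. A count of 0 allows 3 counts, which is 0.1 CPM in the deepest library and 0.448 CPM in the shallowest. Intervals on counts (exact Poisson, 95%) cover counting error only, because reads without molecular identifiers are not independent molecules.

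Changes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr with its default minimum count of 10, which left 20545. Libraries were scaled by TMM, and a robust quasi-likelihood model (glmQLFit, glmQLFTest, two-sided) was fitted with the siRNA group as its only term. Benjamini-Hochberg adjusted p below 0.05 over all genes tested was the threshold. A log2 fold change is TREM2 siRNA over scrambled siRNA. Its SE was approximated as the absolute log2 fold change divided by the square root of the quasi-likelihood F. Levels are CPM on the TMM-scaled library sizes, given as mean ± SD. DESeq2 1.42.0 was an alternative. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All pairs of replicates of 1 group differed by more than sampling noise (chi-square per gene between 4.15 and 16.41), so each library was counted once.

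The labels give each library a batch from 1 to 3, identical to its replicate number, and so pair the scrambled and knockdown libraries. Deviations from the group means did not go together within the pairs (r = -0.03, -0.04 and -0.02 across genes for batches 1, 2 and 3). The fit with the replicate as a block was run as an alternative.

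30 gene lists with 756 members in total were fixed before the data were examined, and 755 members matched a gene of the table. Lists with at least 5 tested members were compared with all other tested genes by camera, with a preset inter-gene correlation of 0.01 and adjustment over the 29 lists tested. The same lists were tested with a correlation estimated from the residuals and with fry. For each list, members past the threshold are given over all genes tested and with the p-values adjusted over the list alone.

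The rule for named genes was also fixed beforehand. TREM2 comes first. It is followed by the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 5 CPM and the same sign in all 3 batches. From each list up to 4 members past the threshold with the smallest p were taken. For a list with none, the 2 members with the highest mean CPM are given as values. Other members of the lists are named to illustrate a group, and genes chosen after their values were seen are said to be so.

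Alternatives fixed beforehand were RLE and upper quartile scaling, DESeq2, no filter, a filter of at least 50 counts in at least 3 libraries, the replicate block, leaving out each library in turn, a threshold of 0.01, and a threshold with an absolute log2 fold change of at least 1. For the lists they also included the estimated correlation, fry, and members held by a single list. Thinning every library to 6689159 counts, and leaving out scrambled replicate 1 and knockdown replicate 2 together, were chosen after seeing the data.

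The fit was tested on simulated counts for the 20545 genes, with 200 genes changed by known folds and the real means and library sizes. Of the changed genes, edgeR recovered 38.6% at 1.5-fold, 67.1% at 2-fold and 81.7% at 4-fold, and 8 of its 131 calls were false. With the gene-wise dispersions of the data in place of the modelled ones, these shares were 42.9%, 72.9% and 88.3%, and 15 of 149 calls were false. In a simulation of the set test, the 1 list of 25 genes shifted by 0.5 (log2) was called, and 0 of 20 random lists were. Genes were drawn independently and no others were changed, so it does not test the preset correlation against correlated genes.

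Words of 7 bases in 3' UTRs were compared with the log2 fold changes in Python 3.11.15 (NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3). The longest annotated 3' UTR of each of 13065 tested protein-coding genes was searched. The shift of a word's carriers was adjusted by linear regression for UTR length, UTR GC content and mean expression, with log2 fold changes limited to 3 in either direction. A planted shift of -0.2 on the carriers of each of 20 words was recovered with a mean of -0.2, and 19 of the 20 intervals of 95% held it. Figures were drawn with Matplotlib 3.10.9.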

Results

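The data are gene counts from 6 poly(A) RNA-seq libraries of THP-1-derived macrophages, all kept in high glucose with TNF-α after transfection. 3 libraries came from cells with scrambled siRNA and 3 from cells with siRNA against TREM2, a lipid-sensing receptor of macrophages and microglia that signals through the adaptor DAP12 (TYROBP). Total counts ran from 6689159 in knockdown replicate 2 to 30149984 in scrambled replicate 2. Mitochondrial transcripts took 8.93%, 4.92% and 5.23% of the counts in scrambled replicates 1, 2 and 3, and 5.86%, 7.02% and 5.59% in knockdown replicates 1, 2 and 3. The design holds a single contrast, TREM2 siRNA against scrambled siRNA. It asks which transcripts of diabetic-type macrophages change when TREM2 is depleted. By itself it cannot tell loss of TREM2 from other effects of either siRNA. Cells without HT are not analysed here, so each change is one within HT-treated cells.

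TREM2 (ENSG00000095970, minus strand of chromosome 6, 41158506 to 41163186, hg38) was lowered to 3.26% of its scrambled level. It stood at 225 ± 33.4 CPM with scrambled siRNA and 7.35 ± 5.38 CPM with TREM2 siRNA (mean ± SD, n = 3 each). The log2 fold change was -5.04 ± 0.563 (SE, edgeR quasi-likelihood test, adjusted p = 0.0043). Raw counts were 1335, 7686 and 5986 in scrambled replicates 1, 2 and 3, against 19, 76 and 185 in the knockdown replicates. Relative to the scrambled library of the same batch, 0.788%, 4.96% and 3.47% of the transcript remained. The level in knockdown replicate 1, 1.47 CPM (95% Poisson interval 0.886 to 2.3), lay below that in replicate 2 (12.0 CPM, 9.48 to 15.1) and replicate 3 (8.54 CPM, 7.35 to 9.86). All 6 libraries fitted their labels.

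**Figure D1:**
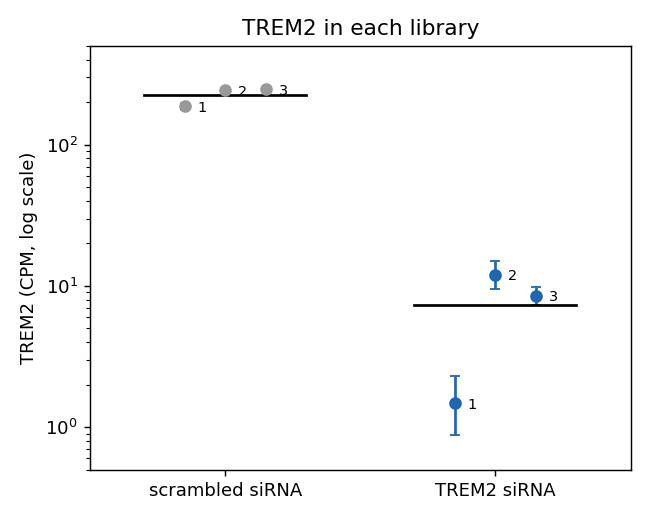
TREM2 in CPM on a log axis for the 3 scrambled and 3 knockdown libraries, numbered by replicate, with 95% Poisson intervals of the counts as bars and the group mean as a black line. The scrambled libraries lie between 187 and 247 CPM and the knockdown libraries between 1.47 and 12.0 CPM.

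A broad part of the transcriptome differed between the 2 siRNA treatments. Of 20545 genes tested, 5928 (28.9%) passed the threshold, with 2933 higher and 2995 lower after TREM2 siRNA (edgeR, adjusted p below the threshold of 0.05). Most changes were small. The median log2 fold change was 0.52 among the genes that rose and -0.73 among those that fell, and 1492 genes changed at least 2-fold, 495 upward and 997 downward. The first principal component of log CPM held 53.4% of the variance and separated the 2 groups.

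The largest changes were ranked among genes past the threshold with a mean of at least 5 CPM and the same sign in all 3 batches. Within these limits, the 10 genes with the largest rise included MYO1D, a class I myosin. MYO1D went from 2.27 ± 0.272 to 34.0 CPM (log2 fold change 3.85 ± 0.185, edgeR adjusted p = 7.4e-11). SPOCK1, a testican proteoglycan, rose by 3.05 ± 0.152 on the log2 scale. The monocarboxylate transporter family member SLC16A6 rose by 2.99 ± 0.158, and the metalloprotease ADAMTS8 by 2.78 ± 0.165. The cytokine gene TNFSF15 (2.49 ± 0.201), STAC2 (2.52 ± 0.183) and TMCC3 (2.43 ± 0.242) followed. HK2, the inducible hexokinase that opens glycolysis, was the most abundant of the 10, at 17.8 ± 0.57 CPM with scrambled siRNA and 95.1 CPM with TREM2 siRNA (2.42 ± 0.0883). The 10 also held 2 genes without a symbol, ENSG00000272079 (2.66 ± 0.212), a long intergenic RNA on chromosome 16, and ENSG00000304416 (2.64 ± 0.215).

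Within the same limits, the 10 largest falls after TREM2 itself were led by F13A1, the A chain of coagulation factor XIII and a marker of alternatively activated macrophages. It dropped from 15.7 ± 2.18 to 0.839 CPM (-4.11 ± 0.234, edgeR adjusted p = 7.4e-10). The fibrillar collagen gene COL11A1 (-3.97 ± 0.276), the calcium channel subunit gene CACNB4 (-3.91 ± 0.158), the carnitine synthesis gene BBOX1 (-3.87 ± 0.31) and the glycosyltransferase gene GALNT16 (-3.79 ± 0.298) fell by similar amounts. TREML1, a TREM family receptor known from platelets, fell from 9.38 ± 2.02 to 0.771 CPM (-3.45 ± 0.314, edgeR adjusted p = 1.6e-07). It lies on the same strand as TREM2, 41149342 to 41154337 on chromosome 6, and starts 4168 bases beyond its end. ROBO4 (-3.19 ± 0.234), the long noncoding RNA XACT (-3.17 ± 0.509), MYOZ2 (-3.11 ± 0.238) and MMP8, neutrophil collagenase (-3.09 ± 0.107), completed the list. The call on XACT was lost when any of the 3 knockdown libraries was left out (edgeR adjusted p of 0.053 to 0.056, with log2 fold changes between -3.22 and -3.11).

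**Figure D2:**
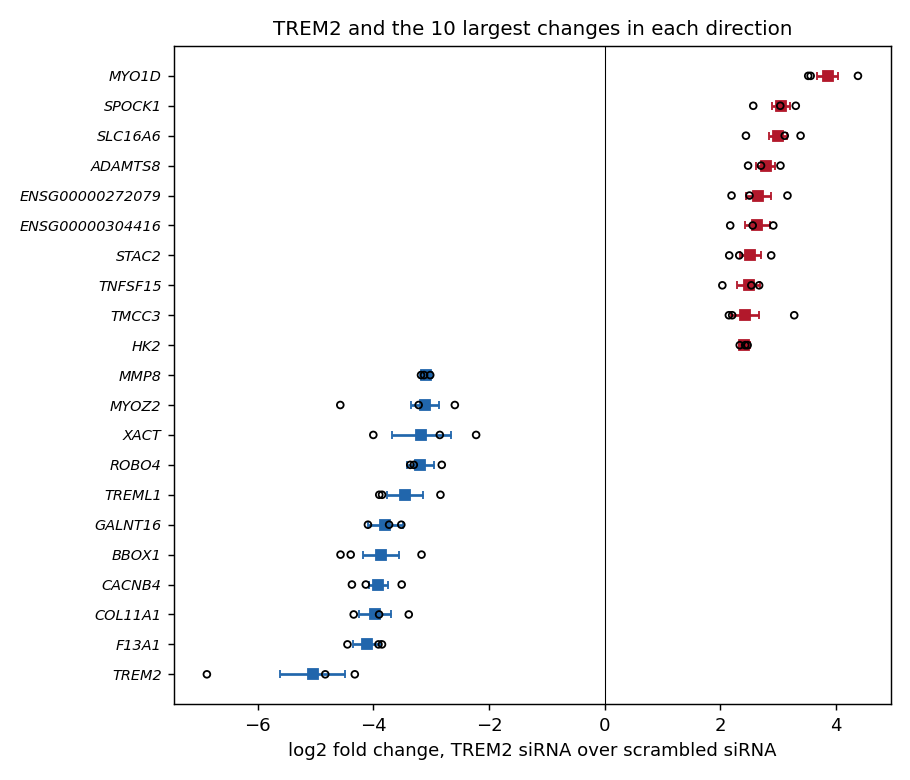
Log2 fold change (TREM2 siRNA over scrambled siRNA) of TREM2 and of the 10 genes with the largest change in each direction. The rule kept only genes past the threshold with a mean of at least 5 CPM and the same sign in all 3 batches. Squares with bars are the fitted value and its SE, red for higher and blue for lower. Open circles are the differences of log2 CPM within each of the 3 batches. Every circle lies on the same side of 0 as its square, which that rule required of all genes but TREM2. Fitted values run from -5.04 for TREM2 to 3.85 for MYO1D.

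Targets of NF-kB and TNF moved up as a group. Of 27 members tested, 16 rose and 2 fell (16 and 3 adjusted over the list alone), with a median log2 fold change of 0.49 (camera adjusted p = 3.5e-05; adjusted p = 0.27 with an estimated correlation). The adhesion receptor ICAM1 rose from 134 to 296 CPM (1.14 ± 0.0744), IER3 from 8.17 to 28.3 CPM (1.76 ± 0.134), and the cytokine IL1B from 453 to 738 CPM (0.70 ± 0.0826). The urokinase receptor PLAUR rose by 0.55 ± 0.074. TNF itself fell by 0.58, and the inhibitor NFKBIA by 0.34. Chemokines were split. CCL3 (0.97 ± 0.135) and CXCL8 (0.91 ± 0.148) rose, while CCL20 (-0.74 ± 0.15) and CCL1 (-1.80 ± 0.474) fell, out of 14 tested. The counts were the same adjusted over the list alone, and the list had a median of -0.12, a mean of -0.02 and an upward but uncalled test (camera adjusted p = 0.88). CCL1 was at most 2.59 CPM, and its log2 fold change was -2.75 without knockdown replicate 3.

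Interferon, inflammasome and antigen presentation genes went both ways. Of 35 type I interferon-stimulated genes, 5 rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.47). With the replicate block 3 rose and 7 fell, as IFI6 and IFIT1 lost their calls (edgeR adjusted p = 0.0568 and 0.111). SAMD9 (-0.90 ± 0.114), IFITM3 (-0.65 ± 0.1), ISG20 (-2.58 ± 0.545) and IFIT3 (-0.49 ± 0.108) were the falls with the smallest p. Among 17 inflammasome and pyroptosis genes, 5 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.76). The pore-forming GSDMD (-0.77 ± 0.132) and the cytokine IL18 (-1.13 ± 0.226) fell, and GSDME (0.67 ± 0.122) and NINJ1 (0.54 ± 0.0997), which ruptures the membrane of dying cells, rose. For MHC class I, 4 of 19 genes rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.64). The peptide transporter TAP2 (0.33 ± 0.0822) and the transactivator NLRC5 (0.49 ± 0.113) rose, and HLA-C (-0.32 ± 0.0726) and HLA-E (-0.34 ± 0.0854) fell. For MHC class II, 2 of 10 genes rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.76), all at low levels. CD86 reached 2.69 CPM (2.08 ± 0.46), LGMN 2.76 CPM (1.44 ± 0.415), and HLA-DRB1 dropped to 5.13 CPM (-0.80 ± 0.199). The LGMN call was lost without knockdown replicate 1 (edgeR adjusted p = 0.052).

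Glycolytic genes were higher after TREM2 siRNA. Of 22 tested, 9 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00014; adjusted p = 0.45 with an estimated correlation). Besides HK2, the regulatory enzyme PFKFB4 (1.73 ± 0.114) and HK1 (0.49 ± 0.0727) rose, with GAPDH going from 804 to 1049 CPM (0.38). PFKP, the platelet-type phosphofructokinase, fell (-0.65 ± 0.0794). Nuclear genes of oxidative phosphorylation shifted slightly upward, with 9 of 33 higher and 0 lower (8 and 0 adjusted over the list alone) and a median of 0.23 (camera adjusted p = 0.0018; adjusted p = 0.7 with an estimated correlation). UQCRC1 (0.45 ± 0.0808), NDUFV2 (0.41 ± 0.0809), NDUFB5 (0.46 ± 0.102) and ATP5F1B (0.39 ± 0.0958) were the clearest. That call was lost in fry (adjusted p = 0.096) and in camera without both of the shallowest libraries (adjusted p = 0.054). Among transcripts encoded in mitochondrial DNA, which varied widely between libraries, 0 of 13 passed the threshold, also adjusted over the list alone (median -0.06, camera adjusted p = 0.95, test upward). MT-CO1 stood at 9614 ± 3380 and 9378 CPM, and MT-ND4 at 8930 ± 3990 and 8618 CPM. Both varied mostly through scrambled replicate 1, without which MT-ND4 was higher after TREM2 siRNA (log2 fold change 0.38, edgeR adjusted p = 0.012).

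Sterol genes rose as a group, while the other lists of lipid genes were not called. Of 25 genes of cholesterol synthesis and uptake, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.013; adjusted p = 0.45 with an estimated correlation). INSIG1, a sterol-responsive brake on SREBP, rose from 59.1 to 186 CPM (1.65 ± 0.0816), and MSMO1 (0.90 ± 0.104) rose too. The sterol carrier STARD4 fell from 48.4 to 16.6 CPM (-1.52 ± 0.105). Among 20 LXR target and lipid efflux genes, 5 rose and 7 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.51). FADS1 (-1.15 ± 0.117), PPARG (-0.76 ± 0.114) and the efflux transporter ABCG1 (-2.84 ± 0.477) fell, and ELOVL5 (0.45 ± 0.0761) rose. The lipid-associated macrophage genes, which accompany TREM2 in adipose tissue and plaques, did not fall as a group. 4 of 23 rose and 7 fell, also adjusted over the list alone (median -0.09, camera adjusted p = 0.4). FABP4, a fatty acid chaperone, dropped from 451 ± 25.1 to 71.0 CPM (-2.69 ± 0.159), and the scavenger receptor CD36 from 1218 ± 33.4 to 669 CPM (-0.86 ± 0.0767). LGALS3 (0.80 ± 0.0771) and the protease CTSB (0.85 ± 0.0966) rose. APOE (-0.03), LPL (-0.10) and GPNMB (-0.09) did not pass the threshold. NRF2 targets included 8 that rose and 2 that fell of 22 (8 and 3 adjusted over the list alone, camera adjusted p = 0.1). GCLC, which limits glutathione synthesis, rose by 0.98 ± 0.0749, HMOX1 by 0.44 ± 0.0798, EPHX1 by 0.50 ± 0.0917 and SRXN1 by 0.45 ± 0.0902.

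The signalling partners of TREM2 had no common direction. Of 22 TREM2-DAP12 pathway genes, 5 rose and 3 fell, also adjusted over the list alone (median 0.00, camera adjusted p = 0.51). The integrin ITGB3 rose from 62.5 to 125 CPM (1.01 ± 0.0969), with GRB2 (0.48 ± 0.0751) and VAV1 (0.51 ± 0.093), and PIK3R1 fell (-0.55 ± 0.077). TYROBP (-0.15) and SYK (-0.19) did not pass the threshold. Phagocytic and efferocytic receptors changed in composition, with 6 of 22 higher and 7 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.51). The scavenger receptor MSR1 fell from 1724 ± 150 to 673 CPM (-1.36 ± 0.0845), and the high-affinity Fc receptor gene FCGR1A by 1.24 ± 0.155. MERTK, which takes up apoptotic cells, rose by 0.82 ± 0.0756, and CD93 by 0.50 ± 0.0724. Lysosomal genes divided almost evenly, with 11 higher and 10 lower of 32, also adjusted over the list alone (camera adjusted p = 0.47). CTSC, which activates serine proteases, fell from 649 to 319 CPM (-1.03 ± 0.0762). SMPD1 (1.02 ± 0.0854) and CTSH (0.57 ± 0.0752) rose.

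Lists of macrophage state markers held genes that rose and genes that fell, and none was called by camera. Of 18 alternative activation genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone). The median was 0.14, the mean -0.08 and the test upward without a call (camera adjusted p = 0.19). FN1 doubled from 335 to 669 CPM (1.00 ± 0.0835), and IL1RN (0.96 ± 0.0895) and the transcription factor MAF (0.96 ± 0.0919) rose, against the fall of F13A1. Of 21 macrophage differentiation markers, 6 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.51). CHI3L1, a secreted glycoprotein of inflamed macrophages, went from 2133 ± 149 to 5537 CPM (1.38 ± 0.1). SLAMF8 (0.79 ± 0.0709) and CSF1 (1.21 ± 0.137) rose as well, while CD109 fell from 1070 to 543 CPM (-0.98 ± 0.0751). Of 14 undifferentiated monocyte markers, 2 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.23, camera adjusted p = 0.43). KIT (-1.84 ± 0.276) and MYB (-1.40 ± 0.221) fell, both below 8 CPM, and TFRC (0.45 ± 0.0716) and FUT4 (0.43 ± 0.0962) rose.

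Secreted angiogenic factors rose more often than they fell. Of 24 tested, 9 rose and 3 fell (9 and 4 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.013; adjusted p = 0.27 with an estimated correlation). VEGFA, the main endothelial growth factor, rose from 21.2 ± 1.47 to 64.3 CPM (1.60 ± 0.103), SEMA3C from 4.88 to 21.2 CPM (2.11 ± 0.147) and WNT5A from 0.408 to 5.68 CPM (3.95 ± 0.35). TNFSF15, which rose as well, is known to restrain endothelial growth, and the 3 members that fell were VEGFC (-0.91), THBS1 (-1.05), itself an inhibitor of angiogenesis, and PDGFA (-0.49). Matrix proteases and their inhibitors changed strongly in both directions, with 7 of 25 higher and 9 lower (7 and 10 adjusted over the list alone, median 0.00, mean -0.41, camera adjusted p = 0.4). The collagenases MMP1, from 706 ± 11.4 to 141 CPM (-2.33 ± 0.0794), and MMP8 fell, as did MMP12 (-2.19). ADAMDEC1 (2.19 ± 0.0966), MMP19 (1.42 ± 0.108) and MMP9 (0.88) rose, and MMP14, the most abundant at 3189 and 3187 CPM, stayed at a log2 fold change of 0.00 ± 0.0932. Among 21 genes of leukocyte adhesion and migration, 5 rose and 9 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.43). With the replicate block 2 rose and 9 fell, as ITGB2, ITGB7 and ITGA5 lost their calls (edgeR adjusted p = 0.0685, 0.0659 and 0.0778). The chemokine receptor CCR1 (1.73 ± 0.0982) and the integrin ITGB1 (0.97 ± 0.0823) rose, and the integrin ITGA4 (-1.01 ± 0.0801) and the fractalkine receptor CX3CR1 (-3.12 ± 0.319) fell.

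Cell cycle genes had the smallest p of the gene lists. Of 34 tested, 28 fell and 0 rose (29 and 0 adjusted over the list alone), with a median log2 fold change of -1.19 (camera adjusted p = 7.3e-33; adjusted p = 0.18 with an estimated correlation). TOP2A fell from 158 ± 8.78 to 43.0 CPM (-1.88 ± 0.0824) and CENPF from 132 ± 16 to 37.8 CPM (-1.78 ± 0.108). The spindle genes TPX2 (-1.50 ± 0.106) and BUB1 (-1.68 ± 0.122) followed. The MCM replication helicase genes moved less, with log2 fold changes from -0.51 to -0.07 over 6 members. Of 27 p53 target and apoptosis genes, 8 rose and 11 fell (9 and 13 adjusted over the list alone, camera adjusted p = 0.64). The antiproliferative BTG2 rose (1.11 ± 0.0706), and BCL2 (-1.21 ± 0.108), GADD45A (-1.22 ± 0.11) and PMAIP1 (-0.87 ± 0.101) fell. Genes of the unfolded protein and integrated stress responses numbered 4 higher and 6 lower of 29, also adjusted over the list alone (camera adjusted p = 0.93). ATF3 (0.84 ± 0.0773), CEBPB (0.95 ± 0.0945) and SESN2 (0.89 ± 0.16) rose, and SEL1L (-0.51 ± 0.073) fell.

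**Figure D3:**
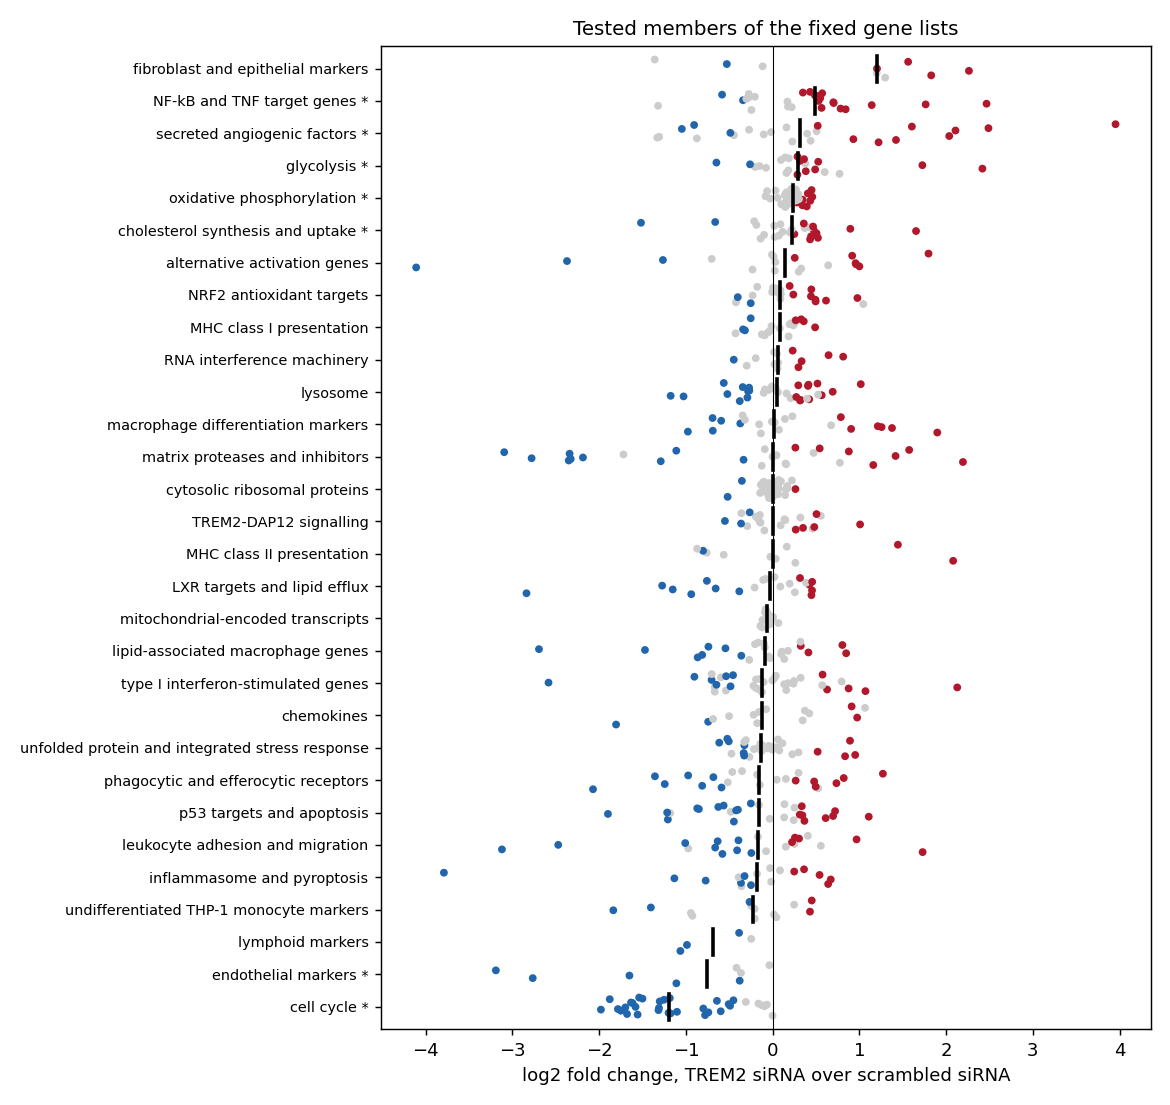
Log2 fold change (TREM2 siRNA over scrambled siRNA) of every tested member of the 30 gene lists, ordered by median. Points are genes, red or blue where past the threshold of 0.05 and grey otherwise. Black bars are medians, and asterisks mark the 7 lists called by camera with the preset correlation. Cell cycle genes have the lowest median, -1.19.

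Markers of other cell types were measured beside these groups. Of 8 tested endothelial markers 5 fell and 0 rose, also adjusted over the list alone, with a median of -0.76 (camera adjusted p = 3.5e-05; adjusted p = 0.27 with an estimated correlation). They were ROBO4, MMRN2 (27.5 to 8.61 CPM, -1.65 ± 0.136), EGFL7 (-1.11 ± 0.113), KDR (-2.77 ± 0.417) and ESAM, and VWF stood at 5.78 and 5.34 CPM. The ESAM call was lost with the replicate block (edgeR adjusted p = 0.0777). Of 9 fibroblast and epithelial markers, 4 rose and 1 fell (6 and 1 adjusted over the list alone, median 1.20, camera adjusted p = 0.19). FAP rose to 15.1 CPM (1.83 ± 0.2), KRT19 (2.26 ± 0.667) and PDGFRB (1.56 ± 0.477) stayed below 2 CPM, and PDGFRA fell (-0.53 ± 0.102). The KRT19 and PDGFRB calls were lost without scrambled replicate 2 (edgeR adjusted p of 0.093 and 0.088), among others. Of the 4 lymphoid markers measured, too few for a list test, IL7R (-0.99 ± 0.156), TRAC (-0.39 ± 0.0776) and GNLY (-1.06 ± 0.263) fell and none rose, with the same 3 adjusted over the list alone. The GNLY call was lost without scrambled replicate 3 (edgeR adjusted p = 0.053) and without knockdown replicate 3 (0.051).

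Ribosomal protein genes and the RNA interference machinery served as references for RNA quality and for the siRNA treatment. Of 43 cytosolic ribosomal protein genes, 1 rose and 2 fell (0 and 2 adjusted over the list alone, median 0.00, camera adjusted p = 0.95). RPL13 (-0.52 ± 0.0976) fell, and RPLP1 (0.26 ± 0.0895) rose. The RPLP1 call was lost with the replicate block (edgeR adjusted p = 0.064) and without scrambled replicates 1 or 2 (0.051 and 0.15). Without knockdown replicate 2 its log2 fold change was 0.16 (edgeR adjusted p = 0.13). Of 13 RNA interference genes, 5 rose and 1 fell, also adjusted over the list alone (median 0.06, camera adjusted p = 0.4). TNRC6A (0.64 ± 0.0889), TARBP2 (0.81 ± 0.148) and AGO2 (455 to 559 CPM, 0.30 ± 0.0841) rose, and DROSHA fell (-0.45 ± 0.122). The AGO2 call was lost without scrambled replicate 2 (edgeR adjusted p = 0.089) and without knockdown replicates 1 or 3 (0.069 and 0.057). DROSHA was at -0.29 without scrambled replicate 1 and lost its call without knockdown replicate 1 (edgeR adjusted p = 0.056).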

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

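Thinning, the omission of both shallowest libraries and the GC correction were chosen after the results were seen. All 7 list calls and the direction of TREM2 held under RLE and upper quartile scaling, no filter, the stricter filter, the replicate block, equal depth and the omission of any single library. TREM2 lay between -5.41 and -4.54, with an edgeR adjusted p from 1.7e-09 to 0.031 and 3.3e-09 in DESeq2. Genes changed numbered 5943 with RLE, 5875 with upper quartile, 5174 in DESeq2 (5067 shared with the 5928), 5480 without a filter, 5289 with the stricter filter and 6857 without both shallowest libraries. Leaving out single libraries gave 4222 to 6147, between 4146 and 5410 of them shared. The replicate block gave 5430, with 5310 shared. It changed 1 call among the genes named by rule, RPLP1 (0.26, adjusted p = 0.064), and no list call. Over all members of the lists, 17 calls were lost with the block and 7 were added. All shared genes had the same sign.

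Some values depended on the threshold, the filter or the set test. Requiring an absolute log2 fold change of at least 1 left 1492 genes, 495 higher and 997 lower, and an adjusted p below 0.01 left 3835, 1840 higher and 1995 lower. Lists called were 7 at first, 12 without a filter, 12 in fry and 0 with an estimated correlation. Fry asks a different question, whether members lean to a side, and lost oxidative phosphorylation. It added phagocytic receptors, leukocyte adhesion and undifferentiated monocyte markers (down, adjusted p = 0.023, 0.032 and 0.0047). It also added alternative activation, NRF2 targets and fibroblast and epithelial markers (up, adjusted p = 0.01, 0.048 and 0.0059). Without both shallowest libraries 10 lists were called, oxidative phosphorylation not among them, and mitochondrial-encoded transcripts were (median 0.22 against -0.06, camera adjusted p = 0.0077). MT-ND4, at -0.05 and not past the threshold, turned to a called 0.26 in that setting. Its log2 fold change ran from -0.25 to 0.38 over the single omissions, the highest without scrambled replicate 1, whose mitochondrial share was 8.93%. The cause was not tested beyond that. Among the genes named by rule, the calls lost in at least 1 setting were those of RPLP1, XACT, KRT19, PDGFRB, AGO2, GNLY, DROSHA, LGMN and CSF1.

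For the number of genes changed, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 5928 genes and the highest of the others 0 (1 split of 10 reached the real count). At equal depth 80.7% of the 5928 genes were called again with the same sign, which argues against depth as the source, as were 27 of the 28 cell cycle genes. Gene length was unrelated to the log2 fold change across genes (Spearman rho -0.023). GC content was weakly related (rho 0.152 over 18225 genes, 88.7% of those tested), between the limits of 0.1 and 0.3 set beforehand, so that test left the question open. After a correction for the GC trend of each library, added for that reason, 90.0% of the 5540 calls among them were made again and rho was 0.005. In the simulation, with 200 of 20545 genes changed, a 1.5-fold change was recovered for 38.6% of genes, or 42.9% with gene-wise dispersions. In these data 28.9% of genes were called, so the adjusted threshold was less strict and those shares do not carry over. How many small changes were missed is therefore not known.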

Other observations

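The gene groups, the words and the tests on TREML1 reads, monocyte markers, GTTTACA and microRNA sites in this part were chosen after the results were seen. The tests of seed matches and of the neighbours of TREM2 were written before they were run. The falls among matrix proteases included a run of neighbouring genes. Between 102520508 and 102955734 on chromosome 11 (hg38) lie 9 MMP genes, of which 7 were tested, 6 fell and 0 rose. The log2 fold changes were -3.09 ± 0.107 (SE) for MMP8, -2.78 ± 0.273 for MMP10, -2.33 ± 0.0794 for MMP1, -2.34 ± 0.558 for MMP3, -2.19 ± 0.169 for MMP12 and -3.75 ± 0.578 for MMP13. MMP7, at the end of the run, was at 0.47 ± 0.236 and did not pass the threshold (edgeR adjusted p = 0.15). The MMP3 call was lost with the replicate block (edgeR adjusted p = 0.194).

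Single genes of coagulation and guidance, picked by their values and not tested as groups, were among those past the threshold. THBD, thrombomodulin, which turns thrombin to an anticoagulant role, rose from 83.4 to 388 CPM (log2 fold change 2.21 ± 0.0728, edgeR adjusted p = 1.3e-12), and the protease inhibitor TFPI2 from 3.28 to 14.1 CPM (2.15 ± 0.185). F13A1, which crosslinks fibrin, fell by 4.11. In plasmin control, PLAU fell (-1.11 ± 0.2), while its receptor PLAUR (0.55 ± 0.074) rose, and SERPINE2 fell (-2.09 ± 0.234). Tissue factor, F3, was at 0.40 ± 0.17 and not past the threshold. SEMA7A rose from 125 to 417 CPM (1.74 ± 0.0794), together with its receptors PLXNC1 (2.31 ± 0.0997) and ITGB1 (0.97 ± 0.0823). The aryl hydrocarbon receptor gene AHR (1.15 ± 0.106) rose with its targets CYP1B1 (1.17 ± 0.0754) and AHRR (0.54 ± 0.0789), though not TIPARP (0.07 ± 0.095).

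The siRNA itself leaves a trace to look for, since a guide strand can repress transcripts that match its seed. The guide sequences are not given in the sources used here, so all 1032 words of 7 bases from the TREM2 transcript with at least 100 carriers were examined in the 3' UTRs. The lowest 95% bound of the shift of any of them was -0.12 (log2), short of the bound of -0.2 set beforehand. That argues against guide seed matches as the source of most of the 2995 falls, 81.1% of which had a UTR to search. Words that the opposite strand of the siRNA would match were not examined. A small contribution stays open, because the lowest of all 15981 words, CCCAGTG (shift -0.07, t = -4.76), is one of TREM2. The TREM2 words CCAGTGA (t = -3.71) and ACCCAGT (t = -3.16) overlap it, at ranks 9 and 34 from the lowest. So does TCCCAGT (t = -3.32, rank 20), which is not a word of TREM2. Among the 100 lowest words 8 were of TREM2, against 6.5 expected. A permutation test with 10000 random word sets gave p = 0.063. With a TREM2 word already lowest, that p-value was set by the share of TREM2 words among all words, so it cannot decide the question.

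The word with the highest score was unrelated to TREM2. Carriers of GTTTACA (2110 genes) lay 0.11 above other genes (log2, 95% interval 0.08 to 0.14, t = 7.28), and 22.7% of them rose past the threshold against 16.6% of other genes. The shares that fell were 19.2% and 18.4%. Together with TGTTTAC (shift 0.10, t = 6.87), it makes up the target site of the miR-30 family, and carriers of the whole 8-base site TGTTTACA (1170 genes) lay 0.136 higher. The reverse complement TGTAAAC had a shift of -0.011 (-0.041 to 0.020), which speaks against a DNA motif that acts in either direction. The 419 other orders of the same bases had a mean shift of 0.002 (95% interval to 0.004, words as the unit), which speaks against base composition. Sites of 21 other microRNA families were shifted by 0.019 on average (0.009 to 0.030, 18 above 0, permutation test with random word sets, p = 0.0012). They were led by let-7 (0.06) and miR-142-3p (0.07). The word ranked next after the miR-30 words, AACACTA (0.088, t = 4.97), overlaps the miR-142-3p site ACACTAC. The mean is too small for an equal loss of activity over all these families to explain the miR-30 value. A loss shared by some families stays open, because it is not known which of them these cells express. A hypothesis is that miR-30 targets were less repressed after TREM2 siRNA, and another that the scrambled guide carries this seed and may lower these genes in the control cells. These data hold no guide sequence and no microRNA levels to separate them.

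The fall of TREML1 alongside TREM2 has several candidate sources. If all TREML1 reads ran on from TREM2 and the siRNA lowered both parts of such transcripts equally, the ratio of their counts would stay the same. Whether it lowers both parts equally was not tested. TREML1 counts per 100 TREM2 counts went from 4.28 to 13.2, a log2 change of 1.62 (95% interval 0.57 to 2.67). In knockdown replicates 1, 2 and 3, with 5, 4 and 28 TREML1 counts, the values were 26.3, 5.26 and 15.1. Under that assumption of equal lowering, the values argue against such reads as the only source of TREML1 counts. Without it, the ratio cannot decide the question. A mixture of them with transcripts of TREML1 itself could also raise the ratio and stays open. Among the other tested genes within 250 kb, NFYA fell (-0.75 ± 0.0848), and OARD1 (0.07 ± 0.139), ADCY10P1 (-0.84 ± 0.352), TREML2 (-0.31 ± 0.528) and TREM1 (the highest, 0.56 ± 0.298) did not pass the threshold. The rule written for this test asked for another gene to rise past the threshold, and 0 did, so lower transcription of the whole cluster stays open. A bound examined only afterwards puts the lowest 95% limit of those genes at -1.53, above 50% of the TREML1 value (-1.73). A dependence of TREML1 on TREM2, and a match of the siRNA to TREML1, were not tested.

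The loss of cell cycle transcripts could reflect fewer undifferentiated monocytes left in the knockdown cultures. The 14 tested markers of such cells had a mean log2 fold change of -0.36 (95% interval -0.76 to 0.03), above the cell cycle median of -1.19. By the rule written for this test that speaks against the explanation. KIT and MYB fell as far as the cell cycle genes, however, while TFRC and FUT4 rose, so the markers did not move as a class and the question was left open. A smaller share of cycling precursors and a slower cycle in all cells therefore cannot be told apart here.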
